A study of Homo sapiens with 6 samples.

How the data were processed

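Total RNA of HuCCT1 cells transfected for 24 h with 2.5 µg of a CASC15 plasmid or a control plasmid was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. There were 3 samples in each group, 1 array each, taken to their groups from the sample titles. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction (version 10.7.3.1, which the submitters' processing notes also name). Per the file headers, the intensities deposited by the authors had been background-subtracted and detrended within the array by that software, on a linear scale and without normalization between arrays. Other values in them are flags, among them those for a spot well above background, saturated or an outlier, as the authors deposited them. Each array holds 62976 spots, of which 61657 are not controls and belong to 50683 probes.

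A table of the authors' own processed log2 values of the same arrays was also deposited. It lists 27977 probes, all found in the scanner files by probe name. Its medians were 0.07, 0.04 and 0.07 in pControl and 0.03, 0.02 and 0.01 in pCASC15. Its log2 changes followed those of the scaled scanner values across probes (r = 0.981, slope 0.991; probes are not independent replicates), which bears out the log2 scale, the direction and the match of names. Each probe had been centred on a baseline that is not the median of these 6 arrays and stays unknown, as does how the probes were selected. The table served as an alternative only.

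Processed intensities were scaled linearly so that all arrays had the same 75th percentile, values under a floor of 10 were set to it, and log2 was taken and expressed relative to the 75th percentile. The floor was set after negative intensities had been seen. Outlier spots were left out, 275 to 443 per array, and spots of a probe were averaged. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which left 27140 probes. For genes with several probes the one of highest mean signal was used, and the text says where others disagree. Probes were named by looking up their accession, without its version, in a RefSeq gene table of assembly GRCh38.p14, another genome build than the array's annotation, so no coordinates are given. Of the 50683 probes, 28174 matched, to 20503 genes, and others kept the name in the files. Of 21689 genes tested, 14719 had a symbol.

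Where a probe was not well above background on any array of a group, the fold is a bound. It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the lowest signal well above background on that array or the probe's own signal, whichever was higher.

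Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is that of the fit and SD that of the 3 arrays of a group. CASC15 was tested at each of its probes, adjusted over all probes kept. Lists of genes, 24 in number, were tested with camera at a preset correlation between genes of 0.01, where at least 5 members were measured. A list's genes were also adjusted over the list alone. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took each CASC15 probe; among genes past the threshold with groups that do not overlap and a gene symbol, the 14 largest rises and 14 largest falls; up to 4 members of each list by smallest p; the measured neighbours of CASC15; and genes fixed by name, among them TGFB1, CXCL8, IL6, CCL2, VIM, CDH1 and SOX4. Rises and falls were ranked by the fitted change, which for values at the floor is no measure of size. Some results that the rule names are not reported. TNFAIP3, IL1A, IFNB1 and IFNL2 lie outside it and were chosen after their values were seen, as were SPOCK2, TCOF1 and the genes named first in the closing section.

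The mean 75th percentile was 1141 in pControl and 1063 in pCASC15, and the mean share of probes well above background was 56.9% and 52.9%. The median processed intensity of negative control spots was -8.32 and -11.0. Spike-in RNA, which the labelling adds in fixed amounts, had a median of -0.79 in pControl and -0.57 in pCASC15 relative to the 75th percentile. The correlation of log2 values across the tested genes, 1 probe each, was 0.996 to 0.998 within groups and 0.993 to 0.995 between groups. The median SD of a gene was 0.07 in pControl and 0.08 in pCASC15. The first principal component held 53.2% of the variance.

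Values were read with data.table (version 1.17.8) and plotted with python 3.11.15. The fit was tested on simulated data for this comparison, with 21687 genes, 200 of them changed. Their values were drawn with independent normal noise from the real pControl means and the spreads that eBayes had estimated. The rates thus hold under the assumptions of the fit and leave out correlation between genes. The fit recovered 76% of genes changed 1.5-fold, 94% at 2-fold, 98% at 4-fold and 100.0% at 8-fold, and 10 of its 194 calls were false.

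The alternatives tried were quantile normalization, scaling to the median of detected probes, normexp background correction (offset 50), no filter on dim probes, detection on all 6 arrays, the mean of a gene's probes, every probe, eBayes with trend and robust settings, array weights, the replicate number as a block, each array left out in turn, the authors' table and minimum folds of 1.5 and 2. For lists they also included an estimated correlation, fry and ranks. Normexp was run on the median spot intensity, in place of the mean planned for it, which the columns given do not hold. A floor of 1, the probe with the smallest change and scaling to the spike-ins were added after seeing the data.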

Results

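RNA was measured in HuCCT1 cells, an established human cell line from an intrahepatic bile duct cancer, 24 h after transfection with 2.5 µg of plasmid. One group of 3 samples received a plasmid that carries the long noncoding RNA CASC15 (pCASC15) and the other group of 3 received a control plasmid (pControl). Each sample was hybridised to its own 1-colour array of 50683 probes. The array's 75th percentile of signal lay between 1009 and 1224 in pControl and between 954 and 1193 in pCASC15, and no spot was saturated. The share of probes well above background was 57.9%, 58.2% and 54.5% on the pControl arrays and 54.3%, 54.2% and 50.2% on the pCASC15 arrays. All 6 arrays were on 1 slide, with pControl in its row 1 and pCASC15 in its row 2, so that slide row and plasmid cannot be told apart. The number of arrays limits the precision. The labels speak of triplicate experiments and not of separate cultures, so p-values measure only the spread between these samples, which may be technical.

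The level of CASC15 was examined first, because it checks the labels of the samples. CASC15 signal was far higher on every pCASC15 array than on every pControl array, at all 3 probes of the gene (NR_015410). Probe A_24_P838448 read -4.21 ± 0.13 (SD, n = 3) in pControl and 8.49 ± 0.15 (SD, n = 3) in pCASC15, on the log2 scale relative to the array's 75th percentile. Its log2 difference was 12.70 ± 0.10 (SE). Probe A_19_P00318323 differed by 12.52 ± 0.09 and probe A_19_P00809119 by 7.30 ± 0.05. The third probe had the highest of the 3 control signals, -0.38 ± 0.05 (SD, n = 3), and all 3 probes were well above background on all 6 arrays. In limma's test over all probes that passed the filter the adjusted p was 6.11e-08, 6.11e-08 and 5.84e-08.

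**Figure D1:**
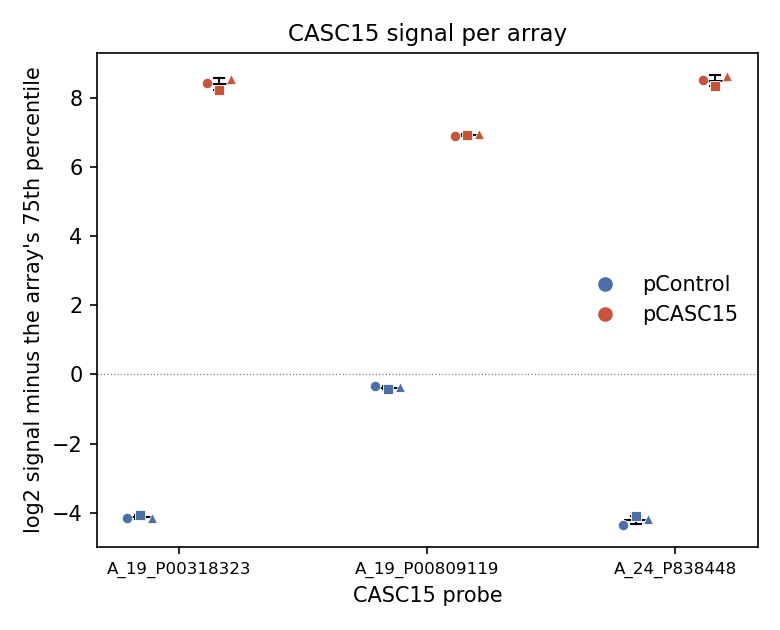
Signal of the 3 CASC15 probes on each of the 6 arrays (y axis, log2 signal minus the array's 75th percentile; x axis, probe). Circles, squares and triangles are replicates 1, 2 and 3, black bars are the group mean and whiskers the SD (n = 3); the pCASC15 means lie 7.30 to 12.70 above the pControl means.

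The genome-wide comparison asked which other transcripts differed between cells given the CASC15 plasmid and cells given the control plasmid. Relative to the 75th percentile, cells that received the CASC15 plasmid had more RNA for many, but not all, measured chemokines, cytokines and interferon-stimulated genes. Single probes for a small set of other genes were many times dimmer. Of 24 gene lists, camera called 10 with a preset correlation between genes and 0 with an estimated one. Of 21689 genes tested, 426 differed at an adjusted p under 0.05 (limma), 200 higher and 226 lower in pCASC15. Of the 251 changed genes with a gene symbol, 152 were higher and 99 lower. Fitted changes reached 1.5-fold in 76 of the higher and 140 of the lower genes, and 2-fold in 28 and 67. With the bound in place of the fitted fold, where no array of the dimmer group was well above background, these counts were 76 and 101 at 1.5-fold and 28 and 42 at 2-fold. An unadjusted p under 0.05 was reached by 3692 genes, against 1084 that chance alone would give. Of the 226 lower genes, 68 were not well above background on any pCASC15 array, as were 13 of the 200 higher genes on the pControl arrays. The higher genes made up 46.9% of the calls, but 58.2% with normexp background correction and 59.6% among genes well above background on all 6 arrays. The count fell to 179, 184 and 149 without pControl replicate 1, 2 or 3, and to 270 and 251 without pCASC15 replicate 2 or 3. All changes are relative to the 75th percentile: scaled instead to the spike-in RNA added to each sample, a choice made after the data were seen, every change was 0.22 lower, the median gene changed by -0.23, and 109 genes were higher and 4346 lower.

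The largest rises among genes with a symbol, apart from CASC15 itself, came from dim probes. Haptoglobin (HP), a plasma protein made by hepatocytes, rose by 2.40 ± 0.17 (log2, SE; adjusted p = 0.0028), from -4.15 ± 0.08 to -1.75 ± 0.35 (SD, n = 3). The homeobox gene SHOX rose by 2.12 ± 0.34, with a SD of 0.72 between its pCASC15 arrays, and LINC00511 by 1.84 ± 0.18 at 1 of its 2 detected probes, while the other differed by -0.17 ± 0.13. A further 6 were not well above background on any pControl array, so that only a lower bound holds: at least 7.63-fold for ZNF610, 8.81-fold for the peptide receptor VIPR2, 4.79-fold for LINC00347, 4.96-fold for PRNT, 2.18-fold for the protocadherin PCDHA4 and 4.13-fold for ZNF577. Of these, ZNF610 ranged from -3.59 to -0.99 over the pCASC15 arrays. In fits that left out 1 array, ZNF577 and SHOX stayed past the threshold in 1 of 6, ZNF610 in 2, VIPR2 in 3 and PRNT and LINC00511 in 5. LINC00347, PCDHA4 and HP did so in all 6. The change of SHOX was 1.82 at its lowest, without pCASC15 replicate 3, and that of ZNF610 was 3.53, without pCASC15 replicate 1.

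Many, but not all, of the measured inflammatory genes were higher in pCASC15. In the list of NF-kB and TNF response genes, 19 of 39 measured genes rose, none fell and 20 did not pass (26 rose when adjusted over the list alone). The chemokine CXCL8, which attracts neutrophils, rose by 1.08 ± 0.09 (log2, SE), its relative CXCL2 by 1.05 ± 0.05, the chemokine CCL20 by 0.95 ± 0.06 and TNF, the cytokine that activates NF-kB, by 0.92 ± 0.05. TNFAIP3, a feedback inhibitor of NF-kB, rose by 0.46 ± 0.05. In the list of cytokines, chemokines and growth factors that epithelia secrete, which shares 10 genes with the former, 17 of 38 rose, none fell and 21 did not pass (23 rose when adjusted over the list alone). IL6 rose by 0.92 ± 0.05, from 4.25 ± 0.07 to 5.17 ± 0.03 (SD, n = 3), CXCL3 by 0.78 ± 0.05, the monocyte chemokine CCL2 by 0.77 ± 0.05 and IL1A by 0.70 ± 0.05. The median log2 change was 0.31 in both lists. Both were shifted upward against the other genes with a preset correlation between genes (camera, adjusted p = 9.9e-25 and 1.5e-23). With an estimated correlation neither passed (adjusted p = 0.073 for each). Scaled to the spike-ins, 10 of the NF-kB genes and 12 of the secreted factors were still higher and 1 of each list was lower, with a median of 0.09 in both; TNFAIP3 then no longer passed (0.24, adjusted p = 0.060). TNFAIP3 also did not pass without pControl replicate 1, 2 or 3 (0.45, 0.46 and 0.47), while CXCL8, CXCL2, CCL20, TNF, IL6, CXCL3, CCL2 and IL1A passed in all 6 fits that left out 1 array.

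Interferon-stimulated genes were higher as well. In the list of interferon-stimulated genes and genes that sense cytosolic DNA, 21 of 43 measured genes rose, none fell and 22 did not pass (42 rose when adjusted over the list alone). The median log2 change was 0.43 and all 43 values were positive. The chemokine CXCL11 rose by 1.14 ± 0.14, the antiviral GTPase MX2 by 0.79 ± 0.06, CXCL10 by 0.79 ± 0.06 and IFI6 by 0.70 ± 0.05. The interferon genes themselves rose too, IFNB1 by 0.84 ± 0.14 and IFNL2 by 0.75 ± 0.11. The probes of IFNB1 and CXCL11 were dim, at -4.55 ± 0.26 and -4.18 ± 0.29 (SD, n = 3) in pControl, though well above background on all 6 arrays. Of the 6 fits that left out 1 array, CXCL11 stayed past the threshold in 2, IFNB1 in 1 and IFNL2 in none. Their lowest values were 0.99, 0.73 and 0.65, each without pControl replicate 3. No member of this list, the NF-kB list or the list of secreted factors was lower at an unadjusted p under 0.05 (0 genes in limma's test). The list was shifted upward (camera, adjusted p = 4.5e-39), and the adjusted p was 0.16 with an estimated correlation. With spike-in scaling 12 of its genes were higher and its median was 0.21.

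**Figure D2:**
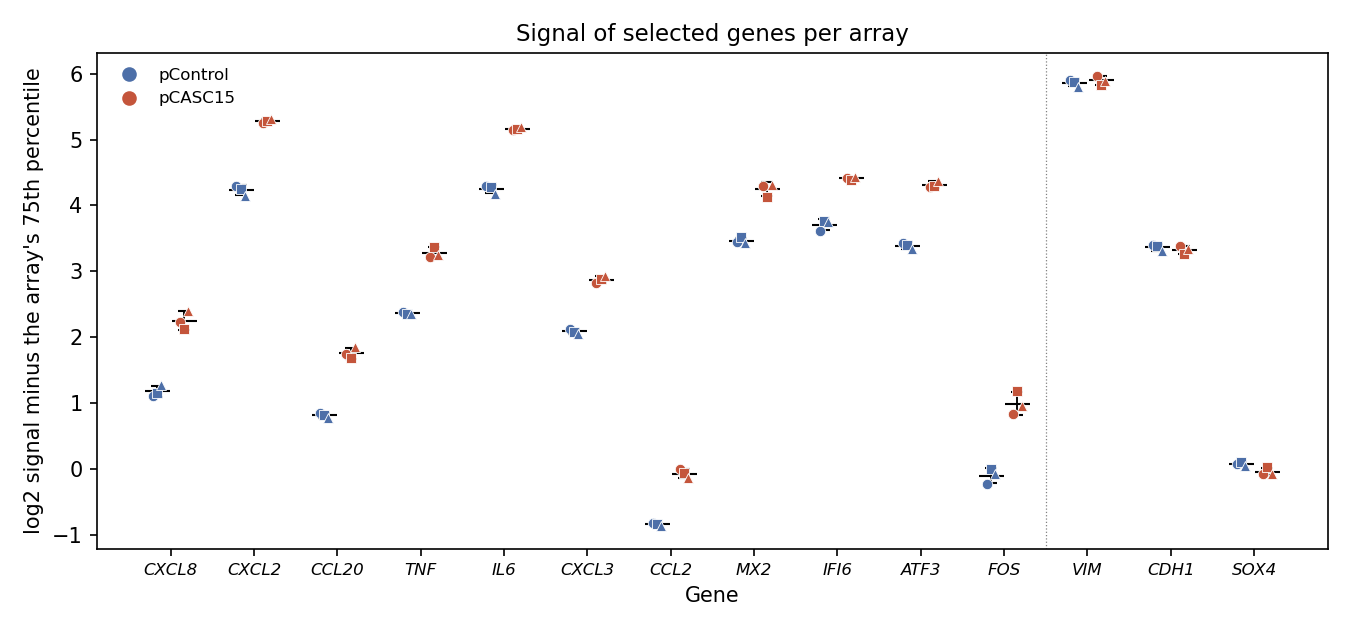
Signal of 14 genes on each of the 6 arrays (y axis, log2 signal minus the array's 75th percentile; x axis, gene). Circles, squares and triangles are replicates 1, 2 and 3, black bars are the group mean and whiskers the SD (n = 3); left of the dotted line the groups do not overlap (CXCL8 by 1.08, IL6 by 0.92), right of it VIM, CDH1 and SOX4 did not pass the test.

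Stress and early response genes rose in part. In the list of ER stress and integrated stress response genes, 3 of 30 rose and none fell (3 adjusted over the list alone): the transcription factor ATF3 by 0.93 ± 0.05, the transcription factor DDIT3, also known as CHOP, by 0.70 ± 0.05 and PPP1R15A, which reverses eIF2alpha phosphorylation, by 0.74 ± 0.11. One of 4 detected ATF3 probes differed by 0.08 ± 0.07 and did not pass. Among immediate early genes, which respond within minutes to growth or stress signals, 5 of 31 rose and none fell (9 adjusted over the list alone), with FOS at 1.09 ± 0.10, EGR1 at 0.61 ± 0.04 and CCN1 at 0.35 ± 0.04. Among replication-dependent histone genes, 6 of 26 rose and none fell (12 adjusted over the list alone), among them H2BC5 by 0.38 ± 0.05 and H2AC7 by 0.34 ± 0.04. H2A and H2B genes are near-identical copies that probes may not separate. Heat shock genes (0 of 21 rose, 0 adjusted over the list alone, 3 at an unadjusted p under 0.05) and metallothioneins with metal response genes (0 of 14; adjusted over the list alone 7 rose and 1 fell; 9 at an unadjusted p under 0.05) had no member past the threshold in limma's test. The medians of these 5 lists were 0.07, 0.11, 0.19, 0.07 and 0.18, but -0.15, -0.11, -0.03, -0.15 and -0.04 with spike-in scaling. The camera adjusted p of their upward shifts was 4.4e-06, 2.9e-06, 9.5e-11, 0.0014 and 0.00089. With an estimated correlation the adjusted p was 0.16, 0.16, 0.32, 0.16 and 0.36. The heat shock shift did not pass with spike-in scaling (adjusted p = 0.18). With that scaling 3 ER stress genes, 3 immediate early genes and 0 histone genes were higher, and 1, 4 and 0 were lower. The heat shock and metallothionein lists each had 0 higher and 1 lower. CCN1 (0.13), H2BC5 (0.17) and H2AC7 (0.12) then no longer passed (adjusted p = 0.20, 0.14 and 0.25). ATF3, DDIT3 and EGR1 passed in all 6 fits that left out 1 array, FOS in all but that without pControl replicate 3 (1.11, adjusted p = 0.056), CCN1 in 2, and PPP1R15A, H2BC5 and H2AC7 in 1. The value of PPP1R15A was lowest, 0.63, without pCASC15 replicate 2.

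**Figure D3:**
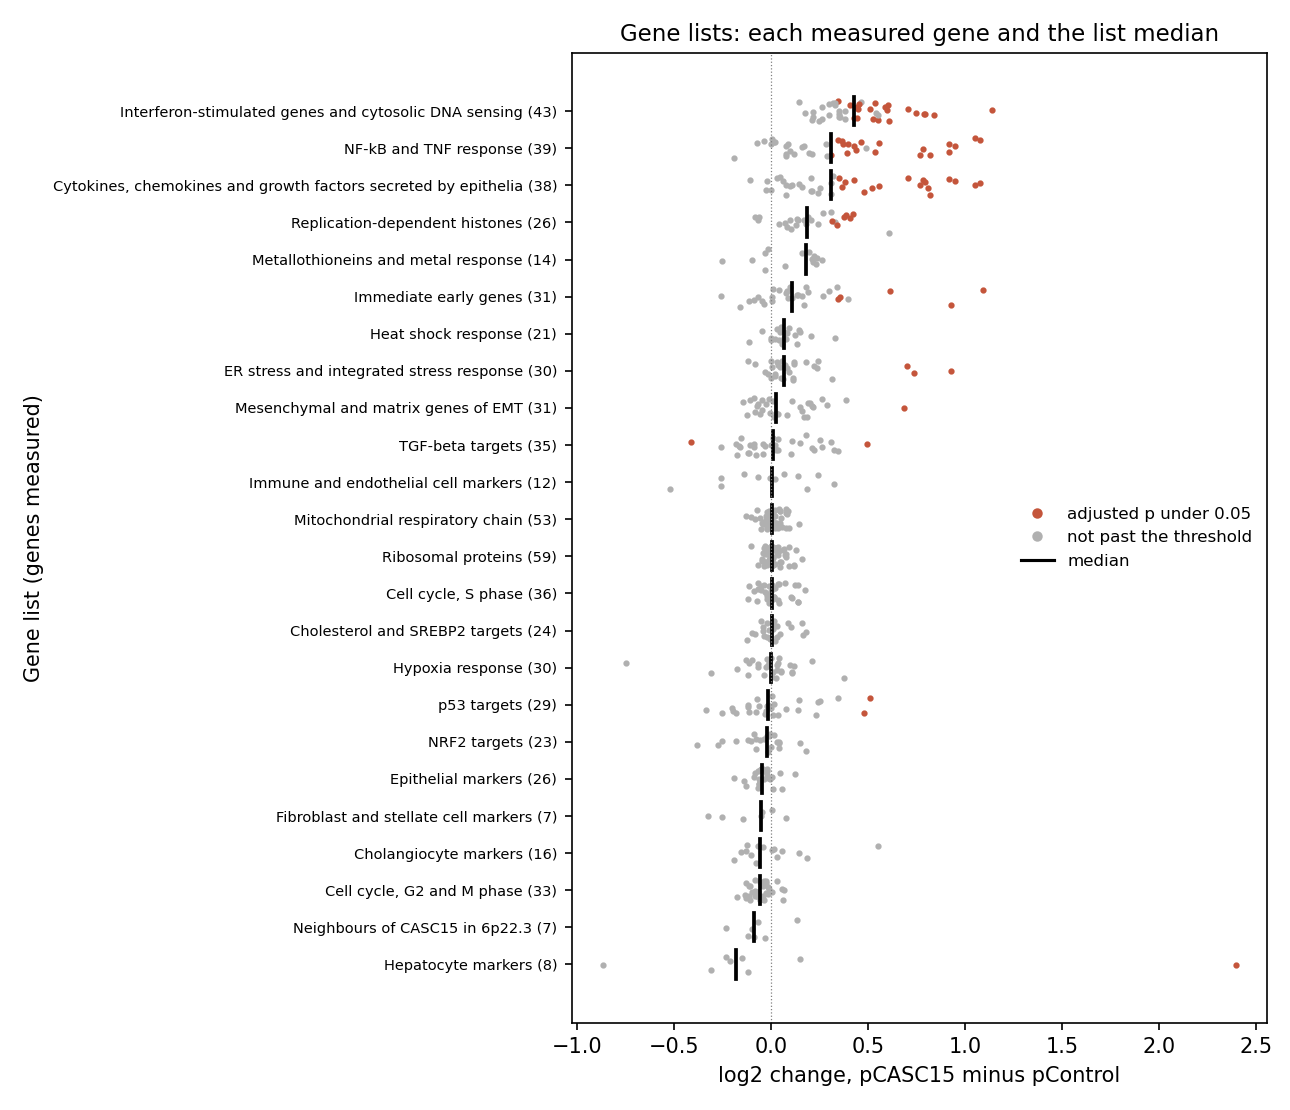
Log2 change between pCASC15 and pControl (x axis) of every measured gene of the 24 lists (y axis, number measured in brackets), with red points past an adjusted p of 0.05 and a black bar at each list's median. A value below the range of the x axis is not drawn; the interferon list has the highest median, 0.43.

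Genes of cell identity, TGF-beta and the cell cycle moved less. Among TGF-beta targets, 1 of 35 rose (CCN2, by 0.49 ± 0.07) and 1 fell (ID1, by 0.41 ± 0.05), with 5 up and 4 down when adjusted over the list alone. CCN2 passed in 1 and ID1 in 2 of the 6 fits that left out 1 array, and CCN2 did not pass with spike-in scaling (0.28, adjusted p = 0.062). TGFB1 itself differed by 0.10 ± 0.09 and was not past the threshold (adjusted p = 0.61). In the mesenchymal and matrix list 1 of 31 genes rose, the matrix metalloproteinase MMP10, by 0.69 ± 0.11 (6 adjusted over the list alone). MMP10 passed in none of the 6 fits that left out 1 array. The camera shift of the list was upward (adjusted p = 0.0070; adjusted p = 0.36 with an estimated correlation), with a median of 0.03 that was -0.19 with spike-in scaling, and the shift did not pass in the authors' table (adjusted p = 0.085). VIM, the mesenchymal filament protein, differed by 0.04 ± 0.06 and CDH1, the epithelial cadherin, by -0.04 ± 0.05 (adjusted p = 0.79 and 0.76). None of 26 epithelial markers passed limma's threshold, adjusted over the list alone included, and 1 did so at an unadjusted p under 0.05. G2 and M phase genes (0 of 33, 0 adjusted over the list alone; 5 at an unadjusted p under 0.05) were shifted downward with a median of -0.06 (camera, adjusted p = 0.014; adjusted p = 0.40 with an estimated correlation). That call ended without pControl replicate 2 (adjusted p = 0.18) or pCASC15 replicate 1 (adjusted p = 0.10). S phase genes (0 of 36, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05) had a median of 0.00357. Scaled to the spike-ins, 9 of 35 TGF-beta targets, 3 of 31 mesenchymal genes and 6 of 26 epithelial markers were lower. So were 14 of 33 G2 and M phase genes and 5 of 36 S phase genes, against 4346 of all 21689 genes tested. With that scaling 1 mesenchymal gene was higher and 0 genes of the other lists of this paragraph.

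The remaining lists were not shifted in camera's test with all 6 arrays and the settings used throughout. Of the p53 targets, 2 of 29 rose (GADD45A by 0.51 ± 0.05 and GDF15 by 0.48 ± 0.05; adjusted over the list alone 4 rose and 1 fell), and the median, -0.02, was opposite in sign to the mean, 0.02, and to the test. With spike-in scaling GDF15 no longer passed (0.26, adjusted p = 0.056). Without 1 array GADD45A passed in 5 and GDF15 in 4 of 6 fits. No gene passed limma's threshold among 30 hypoxia genes (1 up and 1 down adjusted over the list alone; 6 at an unadjusted p under 0.05), 24 cholesterol genes (0; 3), 23 NRF2 targets (0 up and 3 down; 5; shifted downward with normexp, camera adjusted p = 0.040, where 2 fell), 59 ribosomal proteins (0; 0) and 53 respiratory chain subunits (0; 0). The ribosomal list was shifted upward without pControl replicate 3 or pCASC15 replicate 2, with medians that over the 6 such fits lay between -0.0334 and 0.0502. The hypoxia list had a median of 0.00172 and a mean of -0.02. Markers of other cells that a culture could hold were given the same test. None of 12 detected immune and endothelial markers passed (2 up and 0 down adjusted over the list alone, 2 up and 2 down at an unadjusted p under 0.05). The highest was CD74 at 0.32 ± 0.08 (adjusted p = 0.13). None of 7 fibroblast and stellate cell markers passed (2 down adjusted over the list alone), and 1 of 8 hepatocyte markers rose (HP; 2 up and 3 down adjusted over the list alone). The hepatocyte list had a median of -0.18 and a mean of 0.08, and camera put it downward and fry upward (adjusted p = 0.45 and 0.88). The immune and endothelial list had a median of 0.00516 and a mean of -0.02. Of 16 cholangiocyte markers 1 fell and 0 rose (1 up and 1 down adjusted over the list alone), with a median of -0.06 and a mean of -0.50. The camera adjusted p lay between 0.21 and 0.53 in all lists of this paragraph and for the TGF-beta and S phase lists, and was 0.25 for epithelial markers.

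The genes near CASC15 on its chromosome were compared to ask whether they differed along with it. The added CASC15 was carried on a plasmid, so these values cannot speak for or against an effect made at the gene's own locus. None of the 7 measured neighbours passed limma's threshold, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. SOX4, a transcription factor gene, differed by -0.12 ± 0.05 (adjusted p = 0.30), NBAT1 by -0.23 ± 0.09 (0.26), CDKAL1 by 0.14 ± 0.07 (0.39), MBOAT1 by -0.07 ± 0.04 (0.45), E2F3 by -0.10 ± 0.07 (0.55), HDGFL1 by -0.09 ± 0.07 (0.58) and DCDC2 by -0.03 ± 0.09 (0.89). The list's shift did not pass (camera, adjusted p = 0.28; adjusted p = 0.40 with an estimated correlation). With spike-in scaling 3 of the 7 were lower over all genes: NBAT1 at -0.45, SOX4 at -0.34 and MBOAT1 at -0.29 (adjusted p = 0.034, 0.037 and 0.046). The other detected NBAT1 probe differed by 0.11 ± 0.06, so the sign for NBAT1 depends on the probe.

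The falls of largest size were confined to single bright probes wherever a second detected probe allowed a comparison. Falls on the log2 scale (± SE) were seen, each at the gene's only detected probe, for the tachykinin receptor TACR2 (-7.37 ± 0.10), LRRN2 (-5.63 ± 0.23), LINC01088 (-4.71 ± 0.06), SLC24A3-AS1 (-4.31 ± 0.25), CCDC78 (-3.50 ± 0.11), SPRNP1 (-2.27 ± 0.14) and COL10A1 (-1.84 ± 0.24). LINC01347 fell by 5.45 ± 0.09 at 1 probe, while its 6 other detected probes differed by -0.09 to 0.48. CNST fell by 5.18 ± 0.21 at 1 probe, and its 2 others differed by 0.01 ± 0.05 and 0.33 ± 0.09. B3GNT7 fell by 3.78 ± 0.10 at 1 probe and differed by -0.15 ± 0.14 at the other. Over all probes, 31 had a fitted fall of 4-fold or more, 26 of them also with that bound, and 6 of the 26 had another detected probe of the same gene. The 14 other probes of those 6 genes had a median log2 change of 0.12, and none passed the threshold. Among dimmer probes, CATSPERE fell by 1.58 ± 0.15, and ADAMTS10 and ACTR3BP2, not well above background on any pCASC15 array, were lower by at least 1.27-fold and 1.05-fold. COL10A1 stayed past the threshold in 2 of the 6 fits that left out 1 array, ADAMTS10 in 1 and ACTR3BP2 in 2. With normexp background correction ADAMTS10 and ACTR3BP2 changed by -0.09 and -0.39 and no longer passed (adjusted p = 0.53 and 0.078). The offset of 50 in that correction shrinks log2 changes of dim probes whatever their cause.

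**Figure D4:**
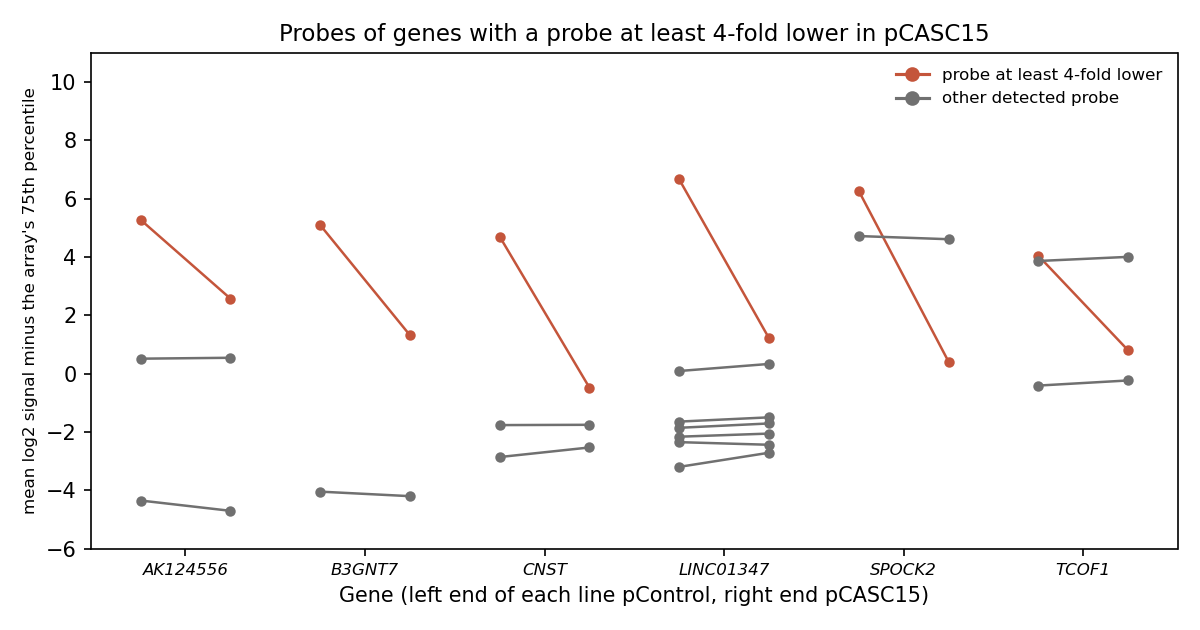
Mean signal (y axis, log2 signal minus the array's 75th percentile) in pControl (left end of each line) and pCASC15 (right end) of each detected probe of the 6 genes (x axis) with 1 probe at least 4-fold lower. The red lines are those probes, with a median change of -4.48, and the grey lines are the 14 other probes of the same genes, which changed by -0.35 to 0.48.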

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

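Scaling to the spike-ins, a floor of 1 and the probe of smallest change were chosen after seeing the data. CASC15 stayed past the threshold and higher at all 3 probes under every alternative run on probes, by 11.51 to 12.77 at the 2 probes of largest change and 7.08 to 7.34 at the other. Against 426 genes (200 higher, 226 lower), the spread model with trend and robust settings called 687 (415 higher), array weights 1417 (595 and 822) and spike-in scaling 4455 (109 and 4346), and detection on all 6 arrays 135 lower. Fitted folds of at least 1.5 left 216 (76 and 140) and of at least 2 left 95 (28 and 67); with bounds for signals not above background the lower counts were 101 and 42. Leaving out 1 array gave 149 to 411 genes, 58 to 178 higher and 89 to 233 lower; fewer samples enter these fits. Normexp called 226 higher and 162 lower, of which 242 were shared with the 426. Other settings stayed within 1.5 times. Where no cause is named, the cause was not tested.

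Same-numbered samples did not deviate together (correlations 0.06, -0.02 and 0.01), so the numbers were not taken to pair the samples. With the replicate number as a block, 103 genes were called (38 higher, 65 lower), 91 of them among the 426, and 10 lists; the block leaves fewer residual degrees of freedom.

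Of 24 lists 10 were called, and 0 with an estimated correlation (camera; 6 at an unadjusted p under 0.05), 14 with fry, which does not compare a list with other genes, and 9 to 11 under all others. The heat shock call ended with spike-in scaling, the mesenchymal call under the authors' table and the metallothionein call with fry. Ribosomal proteins were called upward with array weights, with no filter and without pControl replicate 3 or pCASC15 replicate 2, and NRF2 targets downward with normexp (median -0.0386) and fry. Epithelial, cholangiocyte, fibroblast and neighbour lists were called downward with fry only. Of the neighbours, 1 passed over the list alone with array weights and 5 with spike-in scaling, otherwise 0 (of 10 measured with no filter). Of 74 named genes that were called, 34 were called in all fits without 1 array and 9 in none, and 33 were called with the block. All kept their sign without 1 array, which was fixed in advance because the groups of each do not overlap.

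Results that reversed were uncalled, except LINC00511 (-0.17) and CNST (0.0103) at the probe of smallest change, where by construction another probe is used. That choice gave 0.11 for NBAT1, 0.0664 for E2F3 and a neighbour median of -0.0306 with an upward test. NBAT1 was 0.18 with normexp and -0.30 to 0.16 without 1 array, but the positive values come from its other probe, which was then the brighter: the reported probe had -0.13 with normexp and -0.21, -0.28 and -0.20 without pControl replicate 1, 2 or 3. DCDC2 was 0.00691 with array weights and -0.0927 to 0.0467 without 1 array, and VIM -0.000604 to 0.0720 without 1 array. With spike-in scaling CDKAL1 was -0.0837, TGFB1 -0.11 and VIM -0.18, and the list medians, where the test or its direction turned, were -0.22 for S phase, hypoxia and cholesterol genes, -0.21 for the respiratory chain and -0.40 for hepatocyte markers. Hepatocyte markers had -0.18 with fry, 0.000928 with normexp and -0.0301 with no filter. Ribosomal proteins had -0.0327 with quantile normalization, the respiratory chain -0.0132 with normexp and TGF-beta targets -0.0176 with array weights. Without 1 array, medians were -0.0366 to 0.0306 for TGF-beta targets, -0.0334 to 0.0502 for ribosomal proteins and -0.0177 to 0.0146 for S phase genes. Signal over background limits the dim genes: 68 lower calls were not well above background on any pCASC15 array.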

Other observations

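The genes in this paragraph were chosen after their values were seen. Of 5 measured SPRR2 genes, which encode small proline-rich proteins of the cornified envelope, 4 rose, with SPRR2E at 0.69 ± 0.08 (log2, SE) and SPRR2C at 0.68 ± 0.06. Complement factor CFB rose by 0.62 ± 0.05, the siderophore-binding protein LCN2 by 0.46 ± 0.05 and the pentraxin PTX3 by 0.41 ± 0.05. CD274, the ligand of the immune checkpoint receptor PD-1, rose by 0.65 ± 0.07. Of 4 measured IFITM genes, antiviral membrane proteins, 3 rose, IFITM1 by 0.45 ± 0.07. SPRR2 genes and some IFITM genes are near-identical copies that probes may not separate. In fits without 1 array, SPRR2C and CFB stayed past the threshold in all 6, LCN2 in 4, CD274 in 3, SPRR2E and PTX3 in 2 and IFITM1 in none. LCN2, PTX3 and IFITM1 no longer passed with spike-in scaling. Of 34 measured H2A and H2B genes, 16 rose, none fell in limma's test and 33 values were positive. These values are relative to the 75th percentile, and spike-in scaling, which lowers each by 0.22, ended the call of H2BC5 (0.17) among others.

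In the patterns below, the tests of both explanations of the probe falls, of plasmid DNA, dim signal and array brightness were chosen only after the result was seen. The others were fixed before.

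For 6 genes, 1 probe was at least 4-fold lower in pCASC15 and another probe was detected. The 14 other probes, 6 of them of LINC01347, had a median log2 change of 0.12 where the fallen probes had -4.48. That argues against lower expression of the whole gene, most directly in SPOCK2 and TCOF1, where another probe was closest in level to the fallen one. The other probes of the remaining genes were far dimmer in pControl, as in B3GNT7 (-4.05 against 5.10), and bear on it less. In SPOCK2 1 probe, at 6.27 in pControl, fell by 5.86 ± 0.10 and another, at 4.72, differed by -0.11 ± 0.06. In TCOF1 1 probe, at 4.05 in pControl, fell by 3.24 ± 0.23 and another, at 3.87, differed by 0.14 ± 0.08. RNA made from the control plasmid that binds single probes may account for these falls and would leave the other probes in place, as was seen (0.12), although a change in 1 isoform was not tested. For the 25 other probes with a fitted fall of 4-fold or more, TACR2 included (20 of them also by the bound used for signals not above background), no second detected probe was there to decide, so plasmid RNA and lower expression cannot be told apart. Matching probe sequences to the plasmids would separate them.

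The 27 NF-kB and cytokine genes that rose were picked by their calls under the main scaling. Their median log2 change was 0.52 and stayed at 0.52 under both quantile normalization and median scaling. Those 2 could hardly have lowered it, since the median of all tested genes was -0.0177 and -0.0136 with them, against -0.0122. Scaled to the spike-ins the median of the 27 was 0.30, where 14 still passed and the shift of -0.22 ended the other calls. Scaling was thus argued against as the whole cause for those 14 only. Dim signal was argued against by the median level of the 27, 2.80, above the -0.59 of all tested genes. For immune or endothelial cells, 0% of 12 detected markers (of 22 listed) rose when adjusted over all genes, which met the bound set against them. Adjusted over the list alone 2 of the 12 rose and 0 fell, and CD74 differed by 0.32. The answer thus depends on the adjustment, and such cells are left open. A stronger general response to plasmid DNA in pCASC15 cells remains open and is consistent with the interferon-stimulated genes, whose median rose by 0.43. An effect of CASC15 RNA itself is open and untested, because the design holds no second CASC15 plasmid and no untransfected cells, and slide row is open as well.

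Dim genes were lower in pCASC15: the dimmest 10% of tested genes had a median log2 change of -0.25, with 105 lower and 13 higher calls, and the brightest 10% had 0.01, with 5 and 34. With normexp background correction the dimmest 10% had -0.05, with 37 lower and 17 higher calls. That correction adds an offset of 50, where the scaled signal of these genes was 49.5 in pControl and 42.4 in pCASC15. Such an offset shrinks log2 changes of dim genes whatever their cause, so the smaller shift does not argue for a background effect. Lower overall brightness of the pCASC15 arrays may contribute: at equal 75th percentile the pControl arrays detected 2.65 ± 1.05 percentage points more probes (SE, linear fit on 6 arrays; 95% interval -0.705 to 6.001), which leaves it open. The fit replaced a comparison of pControl replicate 1 and pCASC15 replicate 2, seen first, which with 75th percentiles of 1190 and 1193 detected 57.9% and 54.2%. A lower background level may contribute too, since the shift of negative control spots was 0.462 of the shift of the dimmest 10%, between the bounds set for and against. The filter may contribute as well, which was not tested on the dimmest 10% alone. It kept genes detected in only 1 group, and the pControl arrays detected more probes. With detection on all 6 arrays, 199 genes were higher and 135 lower, and the median of all tested genes was -0.0034, against -0.0122. With no filter, 138 were higher and 171 lower, with a median of -0.0036. None of these can be told apart from a loss of rare transcripts with these 6 arrays.

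The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. The real split called 426 genes, 1 split in 10 called as many, and the highest of the others called 0.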
